A study of Mus musculus with 5 samples.

How the data were processed

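Gene expression was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 array for each of 5 groups of male ddY mice (an outbred laboratory stock) aged 5 weeks. Per the labels, each group had a pair of oral administrations and gut tissue was taken 4 hours after the last one. GA stands for gum arabic, the vehicle, LG21 for Lactobacillus gasseri OLL2716, Asp for aspirin and Tep for teprenone, a mucosal protective drug. Whether an array holds RNA of 1 mouse or of a pool was not given in the sources used here.

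The deposited values are RMA expression values from the Expression Console software, per the labels, while the series' design text names the Affymetrix Exon Array Computational Tool. RMA stands for background correction, normalization between arrays and a summary per probe set. The scale of the deposited values was taken as log2 from the values themselves, which ran from 1.32 to 13.87. Software versions and a genome build were not given in the sources used here. No coordinates are printed, and the RefSeq gene table of assembly GRCm38.p6 served for gene names only. Exact ties between arrays were frequent in the deposited log2 values, with 63.4% of probe sets tied between at least a pair of arrays and 5.78% equal on all 5.

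The table held 35557 probe sets. The platform annotation gave 1 gene symbol for 21789 of them, several for 1621 and none for 12147. Of the single symbols, 21698 were matched to the RefSeq table by gene identifier, 91 were not, and 0 changed. Probe sets naming 1 gene gave 19938 genes. For the 999 genes with several probe sets, the one with the highest mean over the 5 arrays was used. Counts of genes were made among the 9969 genes whose mean lay above the median of all genes, 7.41 on the log2 scale. The authors' normalization was kept. No detection calls were in the table, and differences are given without a fold where a value lay below that of Xist, a gene male tissue does not express.

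Differences of log2 values were taken for 6 pairs of arrays and for the LG21 by aspirin interaction. Genes at least 2-fold apart were counted. With 1 array per group no pair of groups could be tested. A comparison of the 3 aspirin arrays with the other 2, across pretreatments, was not run. No p-value or standard error is given, and the number of arrays limits the precision. For 36 gene lists fixed before the data were examined, of whose 687 symbols 607 genes were measured, the median difference was set against 10000 random lists of the same size matched on deciles of mean expression. Such percentiles describe these arrays alone. Genes of a list are regulated together, so the random lists are narrower than real ones, and between 9 and 15 of the 36 lists lay outside the 2.5th to 97.5th percentile in each comparison, where 1.8 would be expected of lists of unrelated genes. Lists are therefore described mainly where the median differed by at least 0.1. A further 6 lists, of hepatocyte, keratinocyte and clock genes, were written after a first look at the values. Genes called hepatocyte (87) or keratinocyte (58) below come from these added lists and, for keratinocytes, also from the fixed list of squamous epithelium.

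Genes were named by a rule fixed before the data were examined. It took the 10 largest differences each way among filtered genes at least 2-fold apart for the 4 main comparisons, and the 5 largest each way for LG21 against teprenone and for the interaction. It also took genes at least 2-fold apart in both independent aspirin contrasts, genes standing apart in the GA+Asp array, and up to 4 members of each list described. Ptgs1, Ptgs2, Hspa1a, Hspa1b, the Y-linked genes and Xist were always included. Predicted and clone names, chemosensory receptors, immune receptor segments and small RNAs were left out of these picks. Ptgs1, Hspa1b and Ddx3y had no probe set naming them alone and are not analysed here. Other genes named were chosen after their values were seen, as stated beside them.

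Alternatives were no filter, a filter at the 75th percentile, thresholds of 1.5-fold and 3-fold, the mean of all probe sets of a gene, quantile normalization and cyclic loess with 3 iterations. For lists they were the mean in place of the median, filtered members only, the mean of probe sets and cyclic loess. Leaving out hepatocyte and keratinocyte genes and changing the baseline array were added after seeing the data. Where contrasts share an array, 100 simulations of unchanged groups gave the correlation expected from the shared array, with each gene's noise taken from the size of its interaction, so that any real interaction enters as noise. The counting was tested on simulated data for aspirin alone over 9969 genes. All 50 genes planted at 3-fold and all 50 at 2.5-fold were recovered, 0 of 50 planted at 1.5-fold passed the 2-fold threshold, and 4 of 9769 unchanged genes did. For LG21 alone over 19938 genes, 5.5% of 200 simulated lists of 18 genes without a shift lay outside the 2.5th to 97.5th percentile, and 50 of 50 lists shifted by 0.1 lay at or above the 97.5th. Noise in these tests was capped for the most variable genes and drawn independently for each gene. The 4 of 9769 is therefore no rate of false calls for the real arrays. Unshifted lists were random draws set against random draws, so their 5.5% does not carry over to lists of genes regulated together. Work was done with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.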

Results

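Total RNA from the gut of mice was profiled on 5 arrays, 1 for each of the groups GA+GA (vehicle control), LG21+GA, GA+Asp, Tep+Asp and LG21+Asp. There were no replicates, so the differences below are not set against the spread between animals. Array medians lay between 6.95 and 6.98 on the log2 scale. Between 96.1% and 97.6% of filtered genes differed by less than 0.2 in each of the 10 pairs of arrays, and Pearson's r over all probe sets ran from 0.992 to 0.997.

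The list of gastric surface, chief, neck and parietal cells had a median level between 13.03 and 13.05 on each of the 5 arrays. The surface mucin Muc5ac stood at 13.32 in the control, the trefoil peptide Tff1 at 13.33, the gastrokine Gkn1 at 13.28, and Atp4a, the catalytic subunit of the parietal cell proton pump, at 13.45. The 20 measured genes of the list had a median difference of 0.00 with aspirin alone. These genes lie near the top of the scale, which limits how far a lack of difference can be read. The Y-linked genes Uty (9.06), Eif2s3y (9.50) and Kdm5d (8.01) and a low Xist (4.91) in the control matched the label male.

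**Figure D1:**
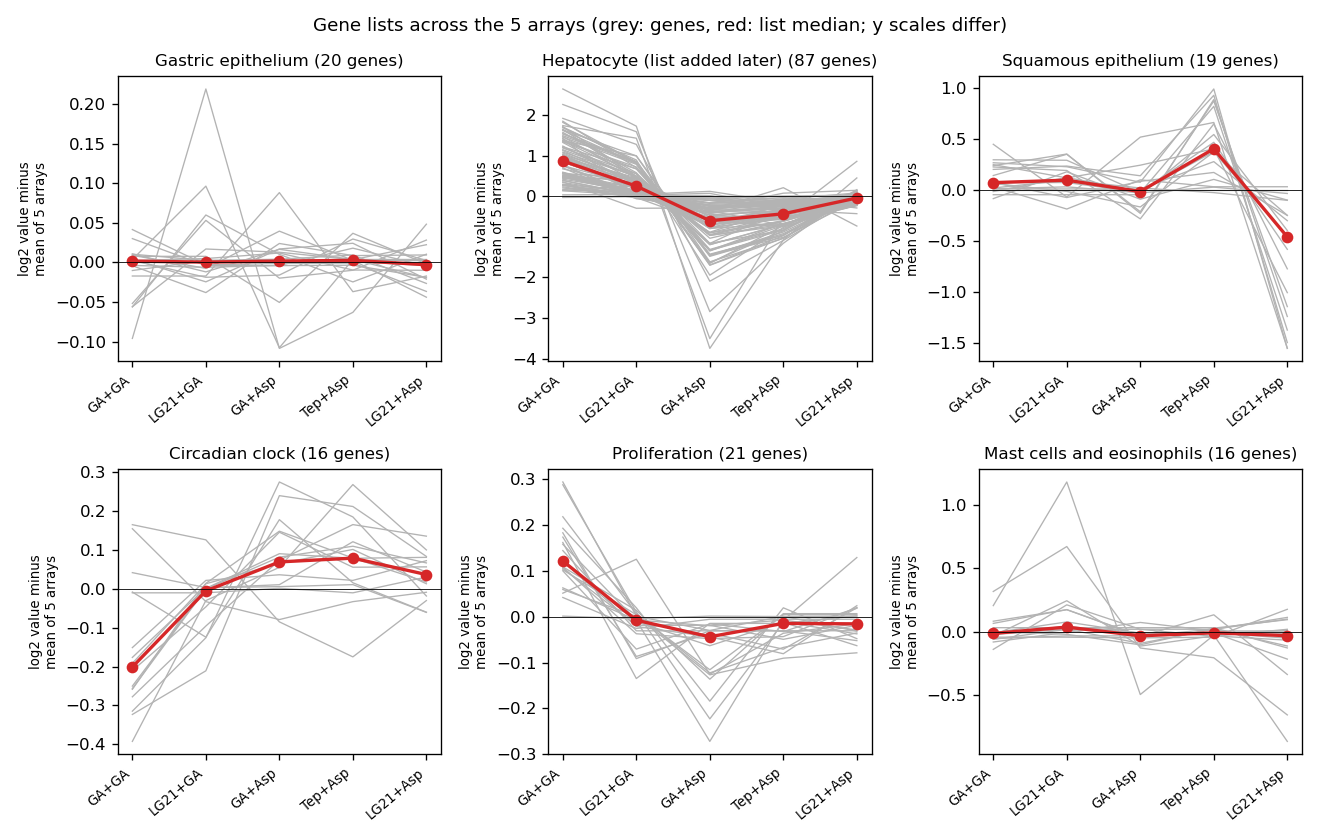
Values of 6 gene lists across the 5 arrays, as the log2 value minus the gene's mean over the arrays (vertical axis; scales differ between panels), with genes in grey and the list median in red. Hepatocyte genes were highest in GA+GA for 83 of 87 genes, and squamous genes were lowest in LG21+Asp for 17 of 19.

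The first comparison asked how the gut transcriptome differed with aspirin alone, GA+Asp against GA+GA. Genes typical of hepatocytes were far lower in the aspirin array. Alb, which encodes serum albumin, stood at 7.43 against 12.69, a 38.1-fold difference. Serpina1c, an alpha-1-antitrypsin gene, stood at 3.91 against 10.31, and no fold is given because 3.91 may not be above background. Pzp, a plasma protease inhibitor, was 16.2-fold lower and the fibrinogen chain gene Fgg 11.5-fold. Cps1, the first enzyme of the urea cycle, was 10.6-fold lower, Mat1a 8.74-fold and the cytochrome Cyp2e1 8.65-fold.

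In all, 32 genes were at least 2-fold lower and 1 was at least 2-fold higher in GA+Asp. Without a filter 103 were lower and 3 higher, and with the stricter filter 8 and 0. Of the 32 lower genes 31 were on the hepatocyte lists, which were partly written from these values. The other was Cwc22, a splicing factor (-1.42), named after its value was seen. Its 8 probe sets ran from -1.42 to -0.90. From high to low its values ranked GA+GA, LG21+GA, LG21+Asp, Tep+Asp and GA+Asp, an order shared by 58 of the 87 hepatocyte genes. Bhmt (-3.05), Fgb (-3.02) and Apoa2 (-2.99) completed the 10 largest, though the mean of Bhmt's 3 probe sets was -2.29. The higher gene was the intestinal alkaline phosphatase Akp3 (8.27 against 7.15, 2.18-fold). Serpina1c and Akp3 belong to families of near-identical genes, so their probe sets cannot be assigned with certainty.

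Smaller shifts of whole lists accompanied aspirin alone. The circadian clock list had a median difference of 0.30, with 13 of 16 genes above 0, led by Bhlhe41 (0.59), Dbp (0.56) and Ciart (0.45). Genes of proliferation had a median of -0.18, with 20 of 21 below 0, among them Ccna2 (-0.51), Rrm2 (-0.43), Top2a (-0.42) and Mki67 (-0.38). In LG21-treated mice the aspirin contrast had a proliferation median of 0.00, with 9 genes above 0 and 10 below. The skeletal muscle list had a median of 0.13 and a mean of 0.25, with Myh8 at 0.91 and Acta1 at 0.80. GA+Asp was strictly highest of the 5 arrays in 10 of its 15 genes. All 3 medians with aspirin alone lay outside the central 95% of matched random lists. Medians were 0.00 for the 27 genes of the prostaglandin and leukotriene pathway, the 27 inflammatory genes, the 17 heat shock genes and the 16 tight junction genes. Exact ties made up 10, 6, 5 and 2 of these genes in that order. The inflammatory list had a median level of 6.60, below the filter level. Both limit how far a lack of difference can be read. Ptgs2, the inducible cyclooxygenase, differed by 0.17 and the heat shock gene Hspa1a by 0.05.

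LG21 without aspirin was compared with the control to ask what the strain does alone. Only 3 filtered genes were 2-fold apart, with 22 without a filter, 0 with the stricter one and 35 at 1.5-fold. Akp3 was 2.59-fold higher in LG21+GA, and the hepatocyte genes Bhmt and Cyp2f2 were 2.33-fold and 2.03-fold lower. The 3 probe sets of Bhmt gave unequal differences, and their mean was -0.81. Below that threshold most hepatocyte genes were lower too, with a median of -0.48 and 48 of 51 below 0 for those not seen before, and -0.66 and 35 of 36 for those seen first. Proliferation genes had a median of -0.15, with 20 of 21 below 0, and clock genes a median of 0.18, with 11 of 16 above 0. GA+GA, which enters this comparison and aspirin alone, was strictly lowest of the 5 arrays in 11 of the 16 clock genes. It had the strictly highest value in 19 of the 21 proliferation genes.

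Some genes of mast cells, cholesterol biosynthesis and the interferon response were higher in LG21+GA, with list medians under 0.1. Mcpt1, a protease of mucosal mast cells, differed by 0.97 from the control and Mcpt2 by 0.35. Of the 16 mast cell and eosinophil genes, 9 were strictly highest in LG21+GA. The 19 cholesterol biosynthesis genes had a median of 0.06, with 16 above 0, and 11 were strictly highest there. Among 19 interferon response genes 12 lay above 0, with Cxcl9 at 0.50 and Iigp1 at 0.31. The median of that list was 0.03, and the inflammatory, macrophage and B cell lists had medians of 0.00. In that order, 8 of 27, 3 of 16 and 9 of 14 of their genes were exactly equal on both arrays.

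LG21 before aspirin, LG21+Asp against GA+Asp, is the comparison named in the series' title. Hepatocyte genes were higher and genes of squamous and cornified epithelium lower in LG21+Asp. The 18 keratinocyte genes not seen before had a median of 0.00, with 5 above 0 and 7 below. Alb was 20.7-fold higher and Serpina1c stood at 8.11 against 3.91, followed by Pzp (2.07), Cps1 (1.80), Mat1a (1.79), Cyp2e1 (1.78), Fgg (1.77), Fgb (1.54), Ahsg (1.44) and Apoa2 (1.41). Krt4, a keratin of stratified epithelium, differed by -2.07 and Serpinb12 was 4.09-fold lower. Genes of the cornified envelope followed, with Lce1c at -1.87, Kprp at -1.65, Lor, which encodes loricrin, at -1.64, Krtdap at -1.63, Crct1 at -1.61, Lce1a1 at -1.55, and Lce1h and Lce1e both at -1.46.

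The 15 genes at least 2-fold higher were all on the hepatocyte lists. Of the 21 lower genes 20 were on the keratinocyte lists, of which the cornified one was written from seen values; the 18 genes not seen before held 0 that were 2-fold lower. The other was the predicted gene Gm94 (-1.06), named after its value was seen. The fixed list of squamous epithelium had a median of -0.45 and a mean of -0.67, with 18 of 19 genes below 0. Filtered members alone gave medians further from 0, here and in the other comparisons described for this list. Skeletal muscle genes had a median of -0.13. Ptgs2 differed by 0.27. Probe sets of the Lce1 family resemble each other closely, so single members are uncertain.

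GA+Asp enters this comparison and aspirin alone with opposite signs. All 15 of the higher genes were among the 32 lower with aspirin alone, against 5.00 in the simulation and 0.0481 for independent lists. The simulation took each gene's noise from its own interaction, which was large for hepatocyte genes, and let genes vary independently. Its 5.00 is therefore no plain chance value. Pearson's r across genes was -0.664, against -0.497 in simulation, and the covariance -0.0161 against -0.00840. Part of the excess over independent lists may come from the shared array. The 32 genes were chosen for a low value in GA+Asp, so the other arrays would lie nearer the control by selection alone. Against the control, they had a median of -2.30 in GA+Asp, -1.91 in Tep+Asp, -1.28 in LG21+Asp and -0.67 in LG21+GA. In LG21+Asp 22 of the 32 were still at least 2-fold below the control, and in Tep+Asp 30 were.

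Teprenone before aspirin, Tep+Asp against GA+Asp, gave the reference drug's difference. Some hepatocyte and keratinocyte genes were higher in Tep+Asp. Of the genes not seen before, 35 of 51 hepatocyte genes lay above 0 and 16 below (median 0.10), and 11 of 18 keratinocyte genes above and 4 below (median 0.05). Alb was 7.87-fold and Pzp 2.01-fold higher, and Serpina1c stood at 6.58 against 3.91. Spink5, a protease inhibitor of the epidermis, was 2.28-fold higher, the keratins Krt1 and Krt10 2.17-fold and 2.12-fold, Lce1e 2.05-fold and Elovl4 2.02-fold. Akp3 was 2.23-fold lower.

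These 9 were the filtered genes at least 2-fold apart with teprenone; there were 20 without a filter, 4 with the stricter one, 41 at 1.5-fold and 2 at 3-fold. Among probe sets naming no single gene, 2 naming several genes and 16 naming no gene were at least 2-fold higher. The squamous list had a median of 0.39, with 16 of 19 genes above 0, yet Krt4 (0.14) and Krt13 (0.16) differed little. Endothelial and fibroblast genes had a median of 0.14, with 13 of 14 above 0, led by Pdgfra (0.40) and Col3a1 (0.25). All 14 smooth muscle genes lay above 0, with a median of 0.06, as did 13 of 16 macrophage and dendritic cell genes, with 0 below. Tep+Asp was strictly highest of the 5 arrays in 13 of 14 endothelial and fibroblast genes and 11 of 14 smooth muscle genes. It was so in 7 of 16 macrophage and dendritic cell genes. These differences may thus come from a single array standing apart. Skeletal muscle genes had a median of -0.15, again with the GA+Asp array that was strictly highest in 10 of 15 genes. Ptgs2 differed by 0.33. With teprenone, 3 of the 8 higher genes were among those lower with aspirin alone, against 5.17 in the simulation. Noise in the simulation included the hepatocyte genes' own interaction, so 3 cannot be called low or high from it.

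**Figure D2:**
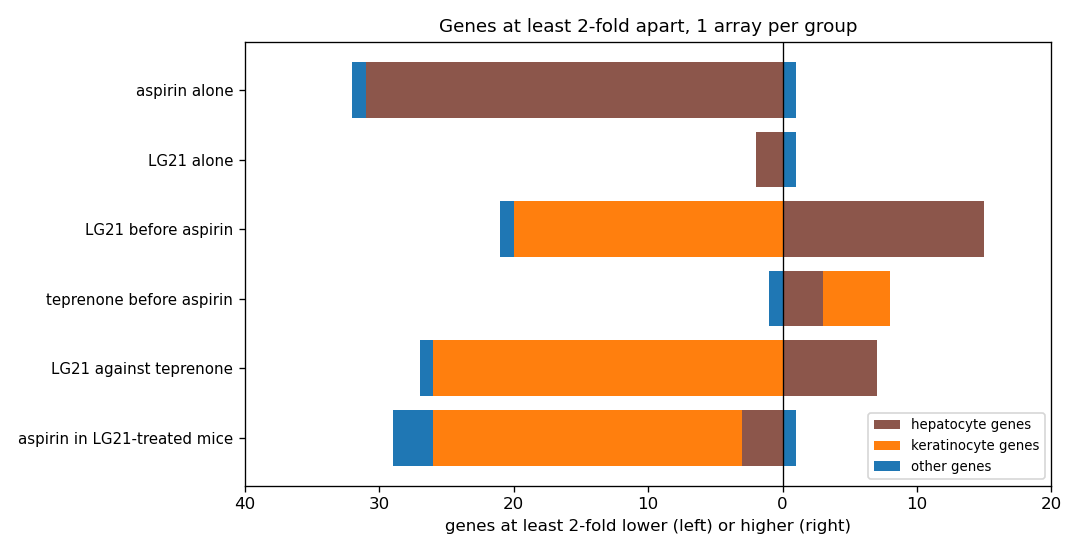
Number of genes at least 2-fold lower (left) or higher (right) in each of 6 comparisons of 1 array with 1 array, coloured by hepatocyte, keratinocyte or other genes. Hepatocyte genes made up 31 of 32 lower genes with aspirin alone, and keratinocyte genes 26 of 27 lower genes in LG21 against teprenone.

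LG21 and teprenone, both with aspirin, differed mainly in keratinocyte genes, which were lower in LG21+Asp. Serpinb12 was 6.54-fold, Lce1c 6.12-fold, Krtdap 5.84-fold, Lce1a1 5.70-fold and Lce1e 5.62-fold lower. Serpina1c was 2.89-fold and Alb 2.63-fold higher, followed by Fgg (1.10), Cps1 (1.07) and Pzp (1.06). In total 27 genes were at least 2-fold lower, 26 of them on the keratinocyte lists but 0 among the 18 not seen before, and 7 were higher. The squamous list had a median of -0.94, endothelial and fibroblast genes -0.13, and wound repair genes -0.12, with Ereg at -0.51 and Thbs1 at -0.28. Tep+Asp was strictly highest of the 5 arrays in 13 of 14 endothelial and fibroblast genes and in 9 of 18 wound repair genes. Against GA+Asp, LG21+Asp had a median of 0.00 for both of these lists. Their differences may thus come from the Tep+Asp array standing apart.

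Aspirin in LG21-treated mice, LG21+Asp against LG21+GA, shares no array with aspirin alone. Keratinocyte genes made up 23 of its 29 lower genes and hepatocyte genes 3. The others, named after their values were seen, were Akp3 (-1.15), Gm94 (-1.36) and Mcpt2 (-1.33), and the single higher gene was Atp6v0d2 (1.19), a proton pump subunit. The 18 keratinocyte genes not seen before had a median of 0.00 here, with 4 above 0, 8 below and 0 at least 2-fold lower. The squamous list had a median of -0.58. Mcpt1, which did not pass the filter, differed by -2.05 and Cxcl9 by -0.95.

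Across genes, which are not independent replicates, the 2 aspirin contrasts had a Pearson r of 0.326 and a Spearman rho of 0.0824. Without hepatocyte and keratinocyte genes r was 0.101, a drop partly built in, since many of them were listed for their differences. Pzp, Serpina1c and Ahsg were at least 2-fold lower in both, and Akp3 was higher in one and lower in the other. The 33 genes of aspirin alone had a median of 2.23 in their own direction and 0.61 in the other contrast, and the 30 genes selected the other way round had 1.35 and 0.09.

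In the LG21 by aspirin interaction, 32 genes were at least 2-fold above 0 and 23 below, a balance that turned to 7 and 13 with the stricter filter. Hepatocyte genes made up 30 of the 32 and keratinocyte genes 21 of the 23, on lists partly written from seen values. Alb (4.68), Fgg (2.75), Pzp (2.71) and Cps1 (2.66) were, beside Serpina1c, the largest above 0, and Akp3 (-2.28), Serpinb12 (-2.03), Lce1c (-2.02), Kprp (-1.81) and Lce1a1 (-1.68) the largest below. Proliferation genes had a median of 0.21, all 21 above 0. GA+GA, which also enters aspirin alone and LG21 alone, was strictly highest in 19 of these 21 genes and strictly lowest in 11 of 16 clock genes. GA+Asp was strictly highest in 10 of 15 skeletal muscle genes. The interactions of these lists may thus come from a single array standing apart. Medians below 0 were found for squamous (-0.46), clock (-0.20), mast cell and eosinophil (-0.13), cholesterol biosynthesis (-0.13) and skeletal muscle genes (-0.12). LG21+Asp was strictly lowest in 17 of 19 squamous and 11 of 19 cholesterol genes. LG21+GA was strictly highest in 11 of 19 cholesterol genes and 9 of 16 mast cell and eosinophil genes. The same limit may therefore apply to these lists. The feedback regulator Insig1 was at -0.52.

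A gene that aspirin alone moves and both pretreatments bring back would stand apart in GA+Asp. Among filtered genes Alb, Serpina1c and Pzp lay at least 2-fold below every other array there, and Pzp, at the threshold against Tep+Asp, dropped out under quantile normalization. The count was 2 in GA+GA, 0 in LG21+GA, 0 in Tep+Asp and 20 in LG21+Asp, where 19 were on the keratinocyte lists. These counts depend on filter and threshold. Without a filter they were 20 in GA+GA, 7 in GA+Asp and 24 in LG21+Asp, and at 1.5-fold 25, 12 and 28.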

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

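Among the tests of this part, those of a substance effect on hepatocyte genes, of the cornified layer alone, of clock phase and of an aspirin effect on the clock were chosen only after the result was seen, as were the use of 95% bootstrap intervals over genes, from 10000 resamples, as the spread of a median and the way these intervals decide the cyclic loess tests. Such an interval gives the spread over the genes of a list on the arrays at hand. Genes of a list are regulated together and are not replicates, so it does not measure the spread between animals or groups.

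Akp3 stood out because aspirin went with opposite differences in the GA-treated and the LG21-treated arrays, 1.12 and -1.15, each at least 2-fold. The interaction was -2.28. With 1 array in each group the difference was not tested.

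The first pattern is the lower level of hepatocyte transcripts in GA+Asp. Scaling or an intensity trend of the kind cyclic loess removes is argued against. The median of the 36 genes seen first, a list written from seen values, was -2.08 before it and -2.10 after (interval -2.70 to -1.53). Liver tissue or RNA in differing amounts is a candidate source: the 51 hepatocyte genes whose values had not been seen had a median of -0.99, at percentile 0.0 of matched random lists, while Alb ran from 7.43 to 12.69. Of the 87, 21 still lay above the filter level, the median of all genes, in GA+Asp. This count cannot tell expression by the gut from remaining liver RNA. An effect of the substances stays open. All 3 aspirin arrays lay below both others for 76 of 87 genes, but no group has a second array. The genes moved together, and 58 of the 87 had the same order, from high to low GA+GA, LG21+GA, LG21+Asp, Tep+Asp and GA+Asp. The 76 genes thus amount to a single ranking of the arrays. LG21+GA, without aspirin, was also below GA+GA in 48 of the 51 genes not seen before.

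Keratinocyte genes lower in LG21+Asp than in Tep+Asp form the second pattern. Scaling or an intensity trend of the kind cyclic loess removes is argued against as the whole cause. The squamous median was -0.94 before it and -0.95 after. Its whole interval, -2.01 to -0.44, lay below the -0.25 that this cause needed. Loess changed list medians little, 9 by more than the small SD of matched random medians and 11 by less, so the test was not a strong one. Different shares of squamous epithelium may account for the pattern, but the test set for this cannot decide it. The 18 keratinocyte genes not seen before lay at percentile 0.01, with a median of only -0.07. Lists of endothelium and fibroblasts (-0.13) and of macrophages and dendritic cells (-0.08) lay at percentile 0.0 in the same comparison. Of the 18 genes 0 were 2-fold lower, many are also made by other epithelia, and against GA+Asp their median was 0.00. A change of the cornified layer alone cannot be told apart from different shares. The median of 6 basal genes was -0.52, past the bound of -0.5 set for excluding such a change, with an interval of -1.24 to -0.07.

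The third pattern is the higher level of clock genes in GA+Asp than in GA+GA, where GA+GA was strictly lowest of the 5 arrays in 11 of 16 clock genes and in all 10 output and repressor genes, and so below LG21+GA as well. A difference in clock phase may account for it: the 4 opposite-phase genes minus the 4 output and repressor genes not seen before gave -0.49 (interval -0.76 to -0.23), which reached past the bound of -0.3, and 6 of the 10 output genes had been seen when the test was set. For an effect of aspirin on the clock, the output genes had a median of 0.0914 in LG21-treated mice (interval 0.04 to 0.17) against 0.35 with aspirin alone. That value met the bound of 0.1 set for excluding the effect, but its interval did not, and the 0.35 rests partly on genes chosen from it. Neither is settled with 1 array per group.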

How the results depend on the processing

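Leaving out hepatocyte and keratinocyte genes and changing the baseline array were chosen only after the data were seen; the other alternatives were planned. No replicate could be left out because each group had 1 array. Quantile normalization and cyclic loess left all 7 counts within 1.5 times. Other baselines gave 23 genes for aspirin alone and 34 for LG21 before aspirin, the latter being LG21 against teprenone itself (7 higher, 27 lower) and so no second estimate. The 23 came from GA+Asp against LG21+GA, which differ in pretreatment too and keep the same GA+Asp array. They are thus no second estimate of aspirin alone either. List alternatives were run only for the 20 list results already picked for a median of at least 0.1 and a place outside the central 95% of matched random lists. All 80 alternatives stayed outside it, which that choice and the narrow random lists make likely. A list median counted as moved when it changed by more than the SD of matched random medians, and 35 of 80 did. Except for fewer or more genes under a filter or threshold, the cause was not tested.

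Without a filter the counts were 106 (aspirin alone), 22 (LG21 alone), 55 (LG21 before aspirin), 20 (teprenone before aspirin), 57 (LG21 against teprenone) and 126 (interaction), and genes standing apart numbered 20 in GA+GA, 7 in GA+Asp and 1 in Tep+Asp. With the stricter filter they were, in the same order, 8, 0, 15, 4, 14 and 20, with 14 for aspirin in LG21-treated mice, and 0 standing apart in GA+GA, 1 in GA+Asp and 12 in LG21+Asp. At 1.5-fold there were 35 for LG21 alone, 57 for LG21 before aspirin, 41 for teprenone, 55 for aspirin in LG21-treated mice and 87 for the interaction, with 25 standing apart in GA+GA, 2 in LG21+GA, 12 in GA+Asp and 11 in Tep+Asp. At 3-fold these counts were 0, 14, 2, 11 and 26, with 0 standing apart in GA+GA and 4 in LG21+Asp. The interaction's 32 above 0 and 23 below became 92 and 34 without a filter, 7 and 13 with the stricter one, 43 and 44 at 1.5-fold and 17 and 9 at 3-fold. The mean of probe sets left 1 standing apart in GA+GA. Without hepatocyte and keratinocyte genes, whose lists were partly written from these values so that lower counts were built in, the counts were 2 (aspirin alone), 1 (LG21 alone), 1 (LG21 before aspirin), 1 (teprenone), 1 (LG21 against teprenone), 4 (aspirin in LG21-treated mice) and 4 (interaction), with 0 standing apart in GA+GA, 0 in GA+Asp and 1 in LG21+Asp. Pearson's r of the aspirin contrasts was 0.308 without a filter, 0.269 with the stricter one, 0.338 with the mean of probe sets and 0.101 without those genes.

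List means in place of medians were -0.21 for proliferation and 0.23 for the clock with aspirin alone, 0.12 for the clock with LG21 alone and -0.17 in the interaction. For squamous genes they were -0.67 (LG21 before aspirin), 0.45 (teprenone), -1.11 (LG21 against teprenone), -0.76 (aspirin in LG21-treated mice) and -0.65 (interaction). Skeletal muscle means were 0.25 (aspirin alone), -0.24 (LG21 before aspirin), -0.27 (teprenone) and -0.23 (interaction), endothelium and fibroblasts -0.15 against teprenone, and mast cells and eosinophils -0.22 in the interaction. Filtered members gave -0.17 for proliferation with LG21 alone, squamous medians of -1.25, 0.85, -2.13, -1.50 and -1.14 in the order above, skeletal muscle medians of 0.30, -0.29, -0.29 and -0.29, and -0.41 for mast cells and eosinophils. Cyclic loess gave -0.19 and -0.15 for proliferation (aspirin alone, LG21 alone), 0.28 for the clock with aspirin alone, -0.10 for cholesterol biosynthesis, squamous medians of -0.43 (LG21 before aspirin), 0.40 (teprenone), -0.95 (LG21 against teprenone) and -0.43 (interaction), and 0.16 for endothelium and fibroblasts with teprenone.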

Other observations

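The single genes and probe sets of this part were chosen after their values were seen, and no test was run on them. Only the enterocyte list had been fixed before.

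Some brush border enzymes of the small intestine differed between arrays. Mgam, a maltase, stood at 6.02 in GA+GA, 6.42 in LG21+GA, 6.31 in GA+Asp, 5.49 in Tep+Asp and 5.78 in LG21+Asp. All these values lay below the filter level of 7.41. Alpi, a close relative of Akp3 with a similar sequence, stood at 7.13, 7.77, 7.37, 7.01 and 7.25. Anpep and Lct differed by 0.11 and 0.00 with aspirin alone, Lct by -0.08 with LG21 alone, and Treh stood at 6.24 on all 5 arrays. The fixed list of 20 enterocyte genes had a median difference of 0.00 with aspirin alone, -0.03 with teprenone before aspirin and -0.08 with aspirin in LG21-treated mice, where 14 lay below 0. The means were -0.44, 0.03 and -0.22 in that order, and 3 genes were at least 2-fold lower with aspirin alone. How far the pattern of the hepatocyte genes enters this list was not tested.

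The interferon-inducible gene Gbp4 stood at 8.13 in LG21+GA and 8.06 in Tep+Asp, against 7.33 in GA+GA, 7.70 in GA+Asp and 7.62 in LG21+Asp. H2-Eb1, an antigen presentation gene, was lowest in GA+Asp (7.57) and stood at 8.16 in GA+GA and 8.52 in LG21+GA. The mast cell carboxypeptidase Cpa3 was lowest in LG21+Asp (8.33), where Mcpt1 (6.40) and Mcpt2 (7.94) were lowest too.

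Probe sets with no listed gene also differed. Of 3176 past the filter, 20 were at least 2-fold lower with aspirin alone, among them one at 4.18 against 12.02, a level too low on the scale for a fold to be given. In all 20 the 3 aspirin arrays lay below both others, and LG21+Asp lay above GA+Asp. These 20 were picked for a low value in GA+Asp, and 14 of them had the order of the arrays described above for 58 of the hepatocyte genes. They are thus no separate sign of an aspirin effect. None of the 3936 probe sets naming no single gene lay at least 2-fold above GA+GA on any of the other arrays.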
